A study of Bos taurus with 21 samples.

How the data were processed

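Small RNA from extracellular vesicles of bovine milk was extracted with a miRNeasy kit and made into libraries with a TruSeq small RNA kit, per the labels' protocols. The series comprises 21 libraries, 7 each from healthy cows, cows with subclinical mastitis and cows with clinical mastitis, and different cows form each group. The submitters' processing notes name Bowtie, edgeR and the cattle genome build ARS-UCD1.2, without versions or roles. Adapter trimming, length filters, the miRNA database and the tool that gave the provisional identifiers are not given in the sources used here. Whether the choice of database and prediction tool accounts for the prevalence of provisional entries was not tested here.

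The authors deposited 1 table of 126 entries by 21 libraries, with 3 further columns that equal the group means to within 4.3e-07. The deposited values are named TPM, but each column sums to 1000000 and holds whole multiples of its smallest value above 0, so that they are RPM values, reads scaled to that sum with no division by length. Of the 629 values above 0, 100% lay within 0.01 of a whole read when divided by that step. The implied reads, 954 to 9587 per library, are the reads assigned to listed entries and not the depth of the libraries. The rule used here for treating RPM values as counts asks for 100 low values per library, which a table this short does not reach. Count models were therefore not run, and the values were tested on a log scale. An RPM value is a share, and a rise of an abundant entry lowers the others. Some entries hold identical values in all libraries, such as 18_29617 and 2_4412 (305 reads each), so their tests are not independent. Of the 79 bovine names, 78 matched a RefSeq gene table of the assembly ARS-UCD2.0, which differs from the authors' build, so no coordinates are given.

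Columns were assigned to samples by name, with the clinical columns carrying a prefix that differs from the sample titles and the same replicate numbers. All 63 pairs of libraries within groups differed by more than counting noise in a chi-square test over entries with at least 10 reads in the pair (lowest chi-square per degree of freedom 1.85).

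Before the data were examined, the groups, tests, lists and most other settings were fixed. The main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPM + 1) with all 21 libraries in 1 fit, moderated contrasts, two-sided p-values and Benjamini-Hochberg adjustment over the entries with a mean of at least 1 RPM, which were all 126. An adjusted p under 0.05 was called a change. The pseudocount is far below the worth of 1 read, so for entries at 0 in some libraries the fitted difference depends on it and can exceed the ratio of the means. Folds against a group at 0 are given against 3 reads over the group. Lists of miRNAs were tested with fry and with camera as an alternative. Differences of profiles and of library measures were tested by exact permutation over all regroupings with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, two-sided for measures. Figures were drawn with matplotlib 3.10.9. Named entries were the 10 largest rises and 10 largest falls per contrast among those that passed with a mean of at least 10 RPM, the 5 with the smallest p where fewer than 5 passed, the 5 most abundant entries and up to 4 members per list.

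The test was tried on 60 simulated sets of clinical against healthy libraries drawn from the real means and implied reads, with 10 of 126 entries changed per set. Among entries with a mean of at least 1000 RPM, which number 20, it recovered 5.43% of 2-fold, 39.6% of 4-fold and 82% of 8-fold changes, and among lower entries 0.197%, 1.64% and 5.8%. None of 60 unchanged sets gave a call, and in the changed sets 31.3% of the calls were entries that had not been changed themselves. The simulated entries varied independently, with a common within-group coefficient of variation of 0.569. The real abundant entries vary together, and other splits of the real libraries did give calls, so these rates need not hold for the real data.

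Alternatives were other scalings, pseudocounts of 0.1 and 10, other filters, 2 groups per fit, limma without trend or with array weights, exact permutation per entry, a fold change minimum, the replicate number as a block, each library left out, and others added after the data were seen.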

Results

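Small RNA was sequenced from extracellular vesicles, membrane-bound particles that cells release, isolated from the milk of 21 cows. The cows were healthy (7), had subclinical mastitis, an inflammation of the udder without visible signs (7), or had clinical mastitis (7), and each cow gave 1 library. The deposited table lists 126 entries, of which 89 carry a miRNA name (79 with the bovine prefix, 7 human, 2 mouse and 1 pig) and 37 carry only a provisional identifier such as X_42271. The files do not pair the provisional identifiers with a gene, a sequence or a position, so these entries are given as listed. Values are RPM, reads scaled to a sum of 1000000 over the listed entries of a library, and their steps imply between 954 and 9587 such reads per library (median 3943), with 954 to 9587 in healthy, 1785 to 4979 in subclinical and 2851 to 5511 in clinical libraries. 1 implied read was therefore worth 104.3 to 1048 RPM, and 76.2% of the 2646 values were 0.

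Provisional entries made up nearly all of the listed reads. The most abundant entry, X_42271, took 26.2% ± 5.43 of the reads in healthy, 27.8% ± 5.21 in subclinical and 34.4% ± 2.39 in clinical libraries (SD, n = 7 each). The next were 16_27381, 2_2827, 17_28610 and X_41367, and 16 entries were above 0 in all 21 libraries. Named miRNAs made up 0% to 0.734% of the reads in healthy libraries, 0.0201% to 0.2% in clinical libraries and 0.1% to 12.7% in subclinical libraries. The upper end in the subclinical group was 1 library, subclinical 4, in which 68 named miRNAs took 381 of 2994 reads (12.7%, exact Clopper-Pearson 95% interval 11.6% to 14%). The other 20 libraries held 0 to 12 named miRNAs each and 91 named-miRNA reads together, 0.111% of their reads. Of the 70 entries above 0 in 1 library only, 50 were named miRNAs found only in subclinical 4. Intervals and detection limits cover counting error only.

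**Figure D1:**
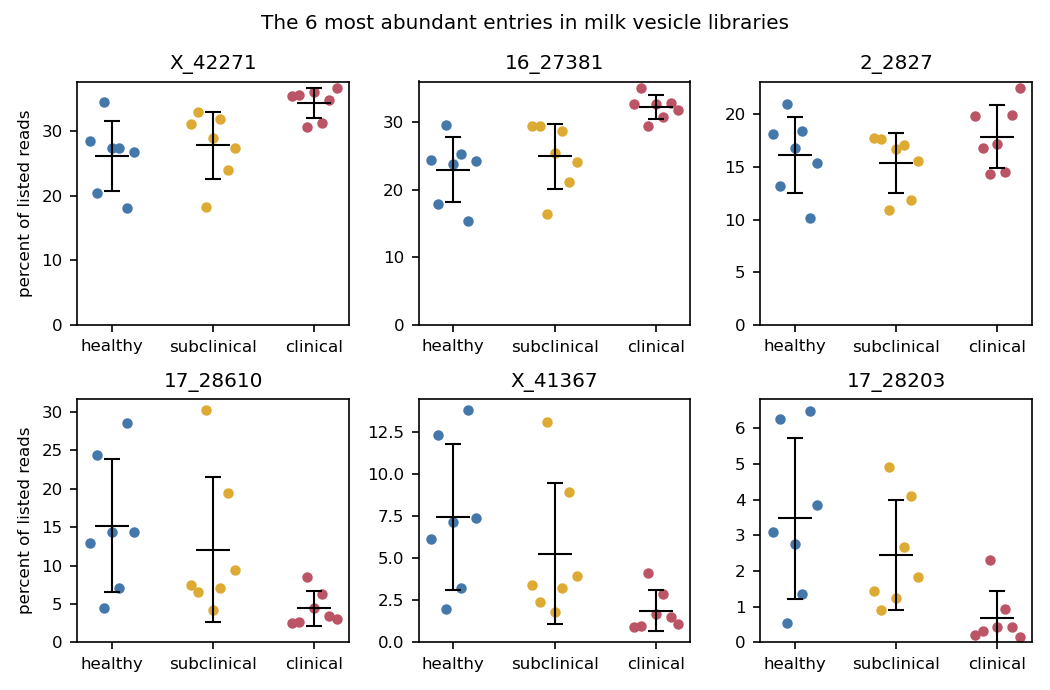
Percent of listed reads (vertical axes, linear from 0) in each of the 21 libraries for the 6 most abundant entries, by group; points are libraries, bars the mean ± SD of 7 libraries, cut off at 0 where the SD exceeds the mean. The 7 clinical libraries lie at 29.4% to 35% for 16_27381 and at 2.47% to 8.48% for 17_28610, against 15.3% to 29.5% and 4.44% to 28.5% in the healthy libraries.

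The comparison of subclinical with healthy milk asked which vesicle miRNAs differ when mastitis shows no visible signs. The entry with the smallest p was miR-21-5p, a miRNA expressed in many tissues and often raised in inflammation, which was above 0 in 7 of 7 subclinical and 2 of 7 healthy libraries. It held 163 of 2994 reads in subclinical 4 (5.44%, exact 95% interval 4.66% to 6.32%), and 1 to 3 reads in each of the other 6 subclinical libraries, 619 ± 348 RPM (SD, n = 6). In healthy libraries it held 5 reads, 4 of them in healthy 5, the library with the fewest implied reads, with a mean of 644 ± 1570 RPM (SD, n = 7). Pooled over libraries, the rate was 545 RPM in the other 6 subclinical libraries (Poisson 95% interval 272 to 975) and 156 RPM in the healthy ones (50.6 to 364). The pooled healthy rate still rests mostly on healthy 5, which held 4 of its 5 reads. An exact permutation test of the log2 values of those 6 against the healthy libraries, chosen after the data were seen, gave an unadjusted p of 0.0186. Among provisional entries, 13_22779 was at 0.34% ± 0.125 of the reads in subclinical against 1.45% ± 0.821 in healthy libraries (SD, n = 7 each), below the healthy mean in 7 of 7.

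No entry passed an adjusted p of 0.05 in limma's moderated test with Benjamini-Hochberg adjustment over 126 entries. An unadjusted p under 0.05 was reached by 6, where chance gives about 6.3. On the log2(value + 1) scale miR-21-5p differed by 7.12 (SE 1.94, adjusted p = 0.0579), 13_22779 by -1.95 (SE 0.61, adjusted p = 0.134), 6_10969 by 2.09 (SE 0.72, adjusted p = 0.214) and 27_38734 by 5.10 (SE 1.87, adjusted p = 0.249). For miR-21-5p and 27_38734 these sizes depend on the pseudocount, since most healthy values were 0 or 1 read. No size is given for miR-26a (adjusted p = 0.342), which was at 0 in all 7 healthy libraries and above 0 in 3 of 7 subclinical libraries. Entry 13_22779 passed in fits of 2 groups (adjusted p = 0.02) and with array weights (0.0385). It also passed in settings added after the data were seen: a minimum mean of 1000 RPM (0.00292), without both subclinical 4 and healthy 5 (0.0476) and with identical entries merged (0.0303). In 34 other alternatives it did not pass. Without healthy 4, healthy 5 or clinical 3 the adjusted p of miR-21-5p became 0.0163, 0.00169 and 0.0205, so that 1 entry passed. It also passed after median-of-ratios scaling (adjusted p = 0.0307), trimmed-mean scaling (0.0174), which shifted the log2 differences by -0.247, with a pseudocount of 10 (0.03), in fits of 2 groups (0.0257), without trend (0.043) and with array weights (0.0385). It did not pass with exact permutation per entry (adjusted p = 0.441), a pseudocount of 0.1 (0.115) or the replicate number as a block (0.198). Nor did it without healthy 1 (0.212), healthy 2 (0.24), healthy 3 (0.113), healthy 6 (0.272) or subclinical 4. Counting the settings added after the data were seen, it passed in 12 alternatives and not in 27. Of the settings added after the data were seen, it passed with a minimum mean of 1000 RPM (0.00487), without both subclinical 4 and healthy 5 (0.00998) and with identical entries merged (0.0303), but not with a pseudocount of 500 (0.356), log2 implied reads as a covariate (0.096) or a slope for them in each group (0.0636). Entry 6_10969 passed in fits of 2 groups (adjusted p = 0.02) and with a minimum mean of 1000 RPM (0.0335), and not in 37 other alternatives.

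The comparison of clinical with healthy milk asked which entries differ in overt disease. Entries 17_28610, X_41367 and 17_28203 fell in clinical milk and 16_27381 rose. The first of these took 15.2% ± 8.66 of the reads in healthy and 4.43% ± 2.23 in clinical libraries, X_41367 7.44% ± 4.34 and 1.88% ± 1.21, and 17_28203 3.48% ± 2.26 and 0.681% ± 0.763 (SD, n = 7 each). Without clinical 4 the clinical mean of 17_28203 was 0.409% ± 0.275 (SD, n = 6). Entry 16_27381 took 22.9% ± 4.8 in healthy and 32.2% ± 1.78 in clinical libraries. All 7 clinical libraries lay below the healthy mean for the 3 entries that fell and above it for the entry that rose. No named miRNA passed, and miR-21-5p was listed at 0 in all 7 clinical libraries, where 3 reads over the group correspond to 102 RPM.

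By limma's test 4 of 126 entries passed, 1 higher and 3 lower, and 9 had an unadjusted p under 0.05, against about 6.3 by chance. The 4 are not separate findings. Within groups the log2 values of the 3 lower entries correlated at r of 0.89 to 0.99 with each other. With 16_27381 they correlated at -0.69 to -0.85. The log2 fold changes were -1.68 for 17_28610 (SE 0.30, 3.21-fold lower, adjusted p = 5.67e-05), -1.95 for X_41367 (SE 0.38, adjusted p = 0.000114), -2.57 for 17_28203 (SE 0.51, adjusted p = 0.000141) and 0.52 for 16_27381 (SE 0.14, 1.43-fold higher, adjusted p = 0.0154). These SEs are moderated, so they borrow from the variance of other entries and are not the spread of each entry alone. Without trend the SEs of the 4, in that order, were 0.558, 0.589, 0.683 and 0.377. Entry 13_22779 was at 0.372% ± 0.148 in clinical libraries (SD, n = 7), a log2 difference from healthy of -1.88 (SE 0.61) that did not pass (adjusted p = 0.0628). It passed without healthy 3 (adjusted p = 0.021), without subclinical 4 (0.014), where only 76 entries were tested, and with array weights (0.0156), which did not converge. Added after the data were seen, it also passed with log2 implied reads as a covariate (0.0235) or with a slope in each group (0.0276), a pseudocount of 500 (0.0216), a minimum mean of 1000 RPM (0.00323), without both subclinical 4 and healthy 5 (0.0131) and with identical entries merged (0.0129). It did not pass in 31 alternatives. Among these were median-of-ratios scaling (adjusted p = 0.169), trimmed-mean scaling (0.188), no trend (0.0871), the replicate number as a block (0.174) and exact permutation (0.0857). Others were the fits without healthy 1 (0.146), healthy 2 (0.242) or healthy 6 (0.215). Exact two-sided permutation tests of single entries gave p = 0.00408, 0.0035, 0.00583 and 0.00117 for the 4 entries in the order above, and none of them passed after adjustment over 126 entries (0.0857, 0.0857, 0.105 and 0.0857). No entry passed when limma's variance was not allowed to depend on abundance or with the replicate number as a block, and the call of 16_27381 was also lost after trimmed-mean scaling (adjusted p = 0.119) and without healthy 2 (0.0597) or healthy 6 (0.0626). Median-of-ratios scaling shifted the log2 differences by 0.241 and gave 2 higher and 3 lower entries, and trimmed-mean scaling shifted them by 0.146 and gave 0 higher and 3 lower.

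The comparison of clinical with subclinical milk asked what separates the forms of mastitis. Named miR-21-5p fell: it was above 0 in 7 of 7 subclinical and 0 of 7 clinical libraries, with 174 and 0 reads. Without subclinical 4 the subclinical libraries held 11 reads among 20197, a pooled 545 RPM (Poisson 95% interval 272 to 975), against 0 of 29434 reads in the clinical group, which allows up to 102 RPM when 3 reads over the group are taken as the limit. The pooled rate of those 6 libraries was 5.34-fold that limit, and the lower end of its interval lies above the Poisson 95% upper limit for the clinical group. With subclinical 4 the pooled rate was 7503 RPM, 73.6-fold the limit. The provisional entries 17_28203, 17_28610 and X_41367 also fell, from 2.44% ± 1.54 to 0.681% ± 0.763, from 12.1% ± 9.41 to 4.43% ± 2.23 and from 5.27% ± 4.18 to 1.88% ± 1.21 of the reads (SD, n = 7 each), with the clinical mean of 17_28203 at 0.409% without clinical 4.

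Those 4 entries, all lower, passed limma's test of 126, and 13 had an unadjusted p under 0.05, against about 6.3 by chance. The 3 provisional entries among them vary together, as given above. The adjusted p was 0.000241 for miR-21-5p, whose fitted log2 difference of -10.02 (SE 1.94) is set by the pseudocount. The log2 fold changes of 17_28203, 17_28610 and X_41367 were -2.19 (SE 0.51, adjusted p = 0.00323), -1.27 (SE 0.30, adjusted p = 0.00323) and -1.38 (SE 0.38, adjusted p = 0.0149). Without trend their SEs were 0.683, 0.558 and 0.589. Entry 16_27381 did not pass (log2 difference 0.39, SE 0.14, adjusted p = 0.178), but it did after median-of-ratios scaling (0.0434), trimmed-mean scaling (0.0454) and rescaling without the most abundant entry (0.0418). It also passed in settings added after the data were seen, with log2 implied reads as a covariate (0.0174) or with a slope in each group (0.0485), and a minimum mean of 1000 RPM (0.0415). In 34 other alternatives 16_27381 did not pass. The exact two-sided permutation p of miR-21-5p was 0.000583, the smallest that its regroupings can give, with and without subclinical 4, but adjustment over 126 entries gave 0.0734. The 3 provisional entries lost the call after median-of-ratios scaling (adjusted p 0.0556, 0.299 and 0.299 for 17_28203, 17_28610 and X_41367) and trimmed-mean scaling (0.131, 0.304 and 0.304), which shifted the log2 differences by 0.272 and 0.393 and gave 1 higher entry, 16_27381, and 1 lower entry each. Rescaling without the most abundant entry gave the same entry higher and 4 lower. In fits of 2 groups, without trend, with array weights and with the replicate number as a block none of the 3 provisional entries passed. With a pseudocount of 500 none of the 4 passed, and miR-21-5p had an adjusted p of 0.0867. The call of X_41367 was also lost without subclinical 3 (0.088), subclinical 6 (0.0792), clinical 1 (0.0729) or clinical 10 (0.0703).

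**Figure D2:**
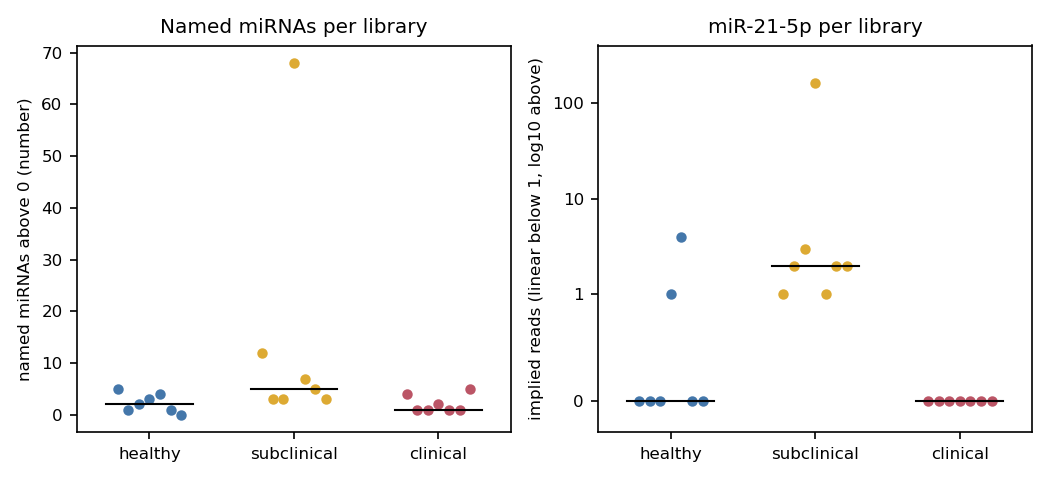
Number of named miRNAs above 0 (left, linear axis) and implied reads of miR-21-5p (right, linear below 1 and log10 above) in each library, by group; points are libraries and lines the group medians. Subclinical 4 holds 68 named miRNAs and 163 miR-21-5p reads, and the 7 clinical libraries hold 0 miR-21-5p reads.

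Groups of miRNAs fixed before the data were examined gave few reads outside subclinical 4. Of 15 lists, 11 had at least 2 measured members, 2 had 1 and 2 had 0, and 33 tests were made. The list of miRNAs abundant in milk had 10 of its 15 members measured: miR-21-5p, miR-30a-5p, let-7f and miR-26a led it, and it held 12 reads in healthy, 252 in subclinical and 3 in clinical libraries, 232 of them in subclinical 4. In that library miR-30a-5p held 28 reads, let-7f 12 and miR-26a 7. The list of miRNAs responsive to inflammation and NF-kB had 4 of 12 members measured, with 5, 179 and 0 reads in healthy, subclinical and clinical libraries, of which 168 were in subclinical 4, and its most abundant members were miR-21-5p, miR-125b, miR-222 and miR-221. The let-7 family held 6, 32 and 2 reads (28 in subclinical 4) and was led by let-7f, let-7b, let-7i and let-7a-5p. The miR-30 family held 1, 50 and 2 (45 in subclinical 4). The clusters related to miR-17-92, led by miR-92a, held 1, 18 and 0 (17 in subclinical 4). The group of miR-10, miR-99, miR-100 and miR-125 held 1, 10 and 0 (8 in subclinical 4).

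Cell type lists were close to the limit of detection. The leukocyte-enriched list, represented by miR-181a and miR-181b, held 0 reads in healthy, 3 in subclinical (2 in subclinical 4) and 0 in clinical libraries. The epithelial list, miR-182 and miR-183, held 0, 5 (4 in subclinical 4) and 0, and the mesenchymal and smooth muscle list, miR-143 and miR-22-3p, 1, 5 (3 in subclinical 4) and 0. The miR-148 and miR-152 list, miR-148b and miR-152, held 0, 4 (all in subclinical 4) and 0. Single measured members stood for the erythrocyte list, miR-16b with 2 reads, and the endothelial list, miR-126-3p with 1 read, all in subclinical 4. The list of entries resembling fragments of other RNAs, led by miR-1246, held 2, 4 (2 in subclinical 4) and 6 reads. The muscle and liver list and the miR-2284 and miR-2285 list had 0 measured members and were not tested.

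No list moved in limma's fry test, which asks whether the members of a list move on balance in 1 direction. The lowest p was 0.0357, for the milk list in clinical against subclinical libraries (adjusted p = 0.393 over 33 tests), and camera gave no list either, with a preset or an estimated correlation. Of its members, miR-21-5p was the one entry that passed, lower in clinical than subclinical milk, both over all 126 entries and adjusted over the list alone. Adjusted over the list alone, miR-21-5p also passed in subclinical against healthy milk. Without subclinical 4 the milk list, with 7 members left above 0, passed in subclinical against healthy (adjusted p = 0.0165) and in clinical against subclinical libraries (adjusted p = 0.00187), a setting chosen after the data were seen. Camera with an estimated correlation did not call it there (adjusted p = 0.777 and 0.472). The list then held 20 reads in subclinical, 12 in healthy and 3 in clinical libraries, and 11 of the 20 were miR-21-5p. Without miR-21-5p as well, fry gave unadjusted p = 0.0119 and 0.00201 for its other 6 members, so the call rests on few reads and on the method.

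Whole profiles differed between clinical and subclinical libraries, though most of the variation lay within groups. An exact permutation test of Euclidean distances on the log2 scale gave p = 0.000583, the smallest its regroupings can give, for clinical against subclinical (12.3% of the variation, adjusted p = 0.00175 over 3 pairs). The p was 0.0221 for subclinical against healthy (11.4%, adjusted p = 0.0332) and 0.0723 for clinical against healthy (10.1%, adjusted p = 0.0723) by the same exact test. With Bray-Curtis distances, which weight abundant entries, the exact p was 0.00233 for clinical against healthy (44.8%) and 0.381 for subclinical against healthy (6.63%). Without subclinical 4 the exact permutation p was 0.0734 for subclinical against healthy and 0.0035 for clinical against subclinical, with Euclidean distances.

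Of 18 tests on 6 measures of library composition, none passed adjustment in exact permutation tests. The most abundant entry of a library took 34.4% ± 2.39 of the reads in clinical and 28.2% ± 3.13 in healthy libraries (SD, n = 7 each; exact p = 0.00291, adjusted p = 0.0525). Libraries listed 26 ± 2.38 entries above 0 in healthy, 37.9 ± 23.6 in subclinical and 26 ± 3.06 in clinical milk (SD, n = 7 each), with 29 ± 3.23 in the 6 subclinical libraries without subclinical 4. The 10 most abundant entries took 96.9% ± 2.29, 95.1% ± 3.33 and 97.6% ± 1.2 of the reads in healthy, subclinical and clinical libraries.

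The log2 differences of subclinical and of clinical milk from the same healthy libraries had a Pearson r of 0.309 and a covariance of 0.507 over 126 entries, which are not independent replicates. Unchanged groups simulated against those healthy libraries gave a mean r of 0.476 (95% range -0.041 to 0.872) and a mean covariance of 0.64. With the healthy libraries split 3 and 4 between the contrasts, r averaged 0.0466 over 70 splits.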

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

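Libraries stood apart from the other 6 of their group in 55 of the values reported, among 99 sets of 7 values with any spread, where chance gives about 5. The measure was the gap of the highest or lowest library to its nearest neighbour, divided by the range of the group. Its limit for 7 libraries was 0.568, and values near 0 make a high ratio easy to reach. Where only 1 of the 7 libraries is above 0 the ratio is 1 by construction. The 55 can therefore not be read as an excess over the 5. The tests weighed here were chosen after the results were seen, except for the ratio to entries outside both sets in clinical against healthy libraries and the distance of subclinical 4, whose predictions were written first.

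Subclinical 4 accounted for 31 of the 55. It listed 91 entries against 34 in the next subclinical library (ratio 0.877) and 68 named miRNAs against 12 (0.862), and named miRNAs took 12.7% of its reads (0.98). Its summed leukocyte-enriched list was at 668 RPM (0.62), its epithelial list at 1336 (0.85) and its erythrocyte list at 668 (1). Among single miRNAs the ratio was 0.984 for miR-21-5p, 0.875 for miR-26a, 0.937 for miR-30a-5p, 0.86 for let-7f, 0.848 for let-7i, 0.747 for miR-30e-5p, 0.916 for miR-92a and 0.62 for miR-143. It was 1, with 0 reads in the other 6, for miR-181b, miR-125b, miR-222, miR-221, miR-182, let-7a-5p, miR-30d, miR-30c, miR-148b, miR-152, miR-25, miR-17-5p, miR-10b, miR-125a, miR-16b, miR-126-3p and miR-2478.

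More implied reads in subclinical 4 are argued against as the cause: 15 other libraries had more, and each listed fewer named miRNAs. The depth of whole libraries was not analysed here and remains open. A candidate explanation is RNA of another source added to an otherwise ordinary library, since over the provisional entries it ranked 3 of 7 by distance from the mean of the other subclinical libraries. The labels give no property of this cow apart from its group, so no biological explanation was tested, and a cow whose milk truly held more miRNA remains open.

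The contrast of miR-21-5p between subclinical and clinical libraries was set against fewer implied reads in the clinical libraries, which is argued against. The clinical libraries held more implied reads, 29434 against 23191 in subclinical libraries, so the totals alone gave this outcome. At the rate of the 6 subclinical libraries other than subclinical 4, the clinical libraries would have given 16 reads, and 0 were seen. These are reads on listed entries, so a difference in the depth of whole libraries remains open. Carry-over of reads from subclinical 4 could not be excluded, because miR-21-5p made up 26.8% of the named-miRNA reads in those 6 libraries and 42.8% in subclinical 4 (Fisher's exact p = 0.0652), and the labels name no sequencing run. A difference between the forms of mastitis also remains open.

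For the 3 provisional entries that were lower in clinical than healthy libraries, a difference in implied reads as the whole cause is argued against. With log2 implied reads as a covariate their median log2 fold change was -2.03 and all 3 passed. Their sum rose with implied reads in healthy (r = 0.795) and not in clinical libraries (r = -0.629), so a slope in each group was also fitted, which gave -1.89 at the mean of the 14 libraries, and again all 3 passed. Implied reads are reads on listed entries and include those of the 3 entries, so the covariate is not independent of what it adjusts. The depth of whole libraries was not analysed for this pattern and remains open. Closure of the RPM scale by the 3 most abundant entries is argued against there, since the ratio to entries outside both sets also fell by 1.84 on the log2 scale (value -1.84, exact permutation p = 0.0111), but not decided against subclinical libraries (value -0.939, exact permutation p = 0.144). The ratio of the 3 most abundant entries to entries outside both sets changed by 0.385 from healthy to clinical libraries (exact permutation p = 0.217), so the rise of 16_27381 is not set apart from closure by the fall of the other 3. Whether X_41367 and 17_28610 are the same reads split in a fixed ratio cannot be told: their ratio varied within counting noise over 21 libraries (chi-square p = 0.24), yet it averaged 40.4% in clinical and 48.3% in healthy libraries (exact permutation p = 0.00699). A difference due to clinical mastitis remains open.

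Other splits of the same 14 libraries, 100 of the 1716 possible for each comparison, gave a bound on chance. For clinical against healthy 1 split, the real one, reached 4 entries, and the highest other gave 3. This bounds chance at 1 in 100 for that count and does not exclude it. For clinical against subclinical 3 splits reached 4, with 6 in the highest other, a share under 0.05. For subclinical against healthy the real count was 0, which any split reaches (100 of 100, with 2 in the highest other), so this comparison is void and chance is left open.

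In healthy 5, the library with the fewest implied reads, miR-21-5p was at 4193 RPM (ratio 0.924), 27_38734 at 2096 (0.813), miR-30a-5p, miR-19a and miR-99b at 1048 each (1), named miRNAs at 0.734% of the reads (0.746) and the 10 most abundant entries at 92% (0.6). Healthy 3 had 34.6% of its reads in the most abundant entry (0.592) and was the only healthy library with miR-2887 (1). Healthy 4 stood apart for 6_10969 at 6345 RPM (0.594) and let-7b (0.832), healthy 1 for miR-143 and miR-1839 (1) and healthy 2 for let-7a-5p (1). Subclinical 8 stood apart for 27_38734 at 3285 RPM (0.637), subclinical 3 for miR-183 (1), subclinical 1 for miR-1246 (1) and subclinical 5 for miR-2887 (1). Clinical 4 had 6_10969 at 31850 RPM against 4173 in the next library (0.886) and 17_28203 at 23160 (0.642). Clinical 1 stood apart for miR-1246 (0.771), let-7b and miR-2887 (1), and clinical 10 for miR-30a-5p (1).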

How the results depend on the processing

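Of 724 alternative values, 614 kept their side of the threshold or their size, and the alternatives named here as added were chosen after the data were seen. No fold change reversed direction. However, filters, fits without trend and leaving out a library of the third group cannot change a fold change. Other values are counts or p-values without a direction, so the absence of reversals is no sign of robustness. For counts of changed entries (0, 4 and 4 for subclinical against healthy, clinical against healthy and clinical against subclinical), median-of-ratios and trimmed-mean scaling gave 1 for subclinical against healthy and 2 for clinical against subclinical, a pseudocount of 10 gave 1 for subclinical against healthy, and fits of 2 groups gave 3 for it and 1 for clinical against subclinical. Limma without trend gave 1, 0 and 1, array weights 2, 5 and 1, and exact permutation per entry 0, 0 and 0, where no adjusted p under 0.0734 is possible for 1 entry alone at the smallest p. Array weights did not converge and gave subclinical 4 almost no weight, and the 2-group fit of clinical against healthy holds mostly entries at 0 in all its libraries, which makes its variance estimate unreliable. The setting without a filter is void, since the minimum of 1 RPM removed no entry, and a minimum of 10, which removed 4, kept the counts. Among the added settings, a pseudocount of 500 gave 0 for clinical against subclinical, a minimum mean of 1000 gave 3, 7 and 7 with fewer entries tested, leaving out both subclinical 4 and healthy 5 gave 2 for subclinical against healthy, as did merging identical entries. Leaving out each library in turn gave 0 to 1, 3 to 6 and 3 to 5. Without subclinical 4 alone (added), 1 list moved by fry in subclinical against healthy and 1 in clinical against subclinical, none by camera with an estimated correlation (lowest adjusted p 0.472), and the profile p for subclinical against healthy was 0.0734. With Bray-Curtis distances the profile p was 0.381 for subclinical against healthy and 0.00233 for clinical against healthy. Mean ranks gave 1 differing library measure in clinical against healthy, where means gave 0. The correlation of both contrasts fell from 0.309 to 0.0466 with split healthy libraries, by the construction of that setting. Other causes were not tested.

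With the replicate number as a block, 0, 0 and 1 entries changed. The numbers mark different cows, and only 1 of 17 same-numbered pairs had deviations correlated above 0.1 (range -0.29 to 0.21). This gives no sign that the numbers pair the samples, but it cannot exclude a factor shared by number. The loss of calls with the block is therefore not set aside. The planned edgeR and DESeq2 tests were not run, because the rule used here asks for 100 low values per library before RPM values are treated as counts. Most named miRNAs held few reads per library outside subclinical 4.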

Other observations

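The relations and measures here were chosen after the data were seen. Named miRNAs together made up 0.0797% ± 0.0736 of the reads in clinical and 2% ± 4.73 in subclinical libraries (SD, n = 7 each; exact permutation p = 0.00932, adjusted p = 0.035 over 15 tests). Without subclinical 4 the subclinical share was 0.209% ± 0.0869 (SD, n = 6; exact permutation p = 0.0151, adjusted p = 0.0455). The 15 tests include summed shares of abundant entries that were chosen from these same data. Their low p-values lower both adjusted p-values, so neither is read as a pass. Healthy libraries were at 0.171% ± 0.259 (SD, n = 7), against which the clinical share had an exact permutation p of 0.525. Without healthy 5 the healthy share was 0.0767% ± 0.0793 (SD, n = 6; exact permutation p = 0.956 against clinical libraries).

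The 3 most abundant entries, X_42271, 16_27381 and 2_2827, and the next 3, 17_28610, X_41367 and 17_28203, varied in opposite directions between cows. Over 21 libraries the summed percent of the former and of the latter had a Pearson r of -0.954 and a Spearman rho of -0.935 (permutation p = 1e-05 each, the smallest that 100000 resamples can give, adjusted 8e-05 over 8 relations), and r of -0.916 without the 2 libraries farthest from the median. Within groups of 7, r was -0.969 in healthy (exact p = 0.000397, rho -0.964), -0.935 in subclinical (exact p = 0.00813, rho -0.786) and -0.943 in clinical libraries (exact p = 0.00357, rho -0.821). Without the 2 farthest libraries r was -0.933, -0.22 and -0.532, so within the subclinical and clinical groups the relation rests on those libraries. Both sums are shares of 1 total and together take most of it, which favours a negative relation without any biology. The latter sum was also set against log2 implied reads. Implied reads include the reads of these 3 entries, which by itself favours a positive relation. In healthy libraries r was 0.795 (exact p = 0.0288, adjusted 0.0461; rho 0.893, adjusted 0.0328; r 0.856 without the 2 farthest libraries). It was 0.665 in subclinical (exact p = 0.0883, adjusted 0.101; rho 0.679), -0.629 in clinical (exact p = 0.128, adjusted 0.128; rho -0.607) and 0.446 over all 21 libraries (permutation p = 0.0429, adjusted 0.0572; rho 0.236). The sum was 26.1% ± 15.2 of the reads in healthy, 19.8% ± 15 in subclinical and 6.99% ± 4.16 in clinical libraries (SD, n = 7 each). Its members are the 3 entries called lower in clinical libraries in both contrasts. A test of the sum restates those calls, so its p is not given.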
